A study of Homo sapiens with 12 samples.

How the data were processed

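Messenger abundance was measured by RNA sequencing in 12 libraries of A375 cells, 3 in each of 4 groups that combine control or OGDH-depleted cells with glucose or with 5 h of glucose starvation. Groups and replicate numbers were taken from the sample titles. The deposited table holds raw counts of fragments per gene name, made by the authors with featureCounts 2.0.1, per the file headers. Fragments were counted as pairs over exons, grouped by gene name and without using strand, and those mapping to several places or overlapping several genes were left out, per the file headers. Subread and the hg38 build are named in the submitters' processing notes. The aligner, the read trimming and the kind of library (poly-A selected or ribosomal RNA depleted) are not given in the sources used here.

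This counting shapes several measurements. Near-identical copies such as HSPA1A and HSPA1B, HSPA6 and HSPA7, or GLUD1 and GLUD2 lose shared fragments, so their levels are uncertain. Without strand, fragments from exons where a gene and its antisense partner overlap cannot be assigned and were left out, so both lose counts there. Because genes were grouped by name, 80 names lie on more than 1 chromosome.

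The counts were taken as deposited, with 61209 gene names and total counts of 21556273 to 25546615 fragments per library. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total count 15, over the 4 groups), which left 18526 gene names holding 99.9% of all counts. The other 42683 were not tested. Counts were scaled by TMM factors, and levels are given as CPM, the count relative to the scaled library size. Each ± is the standard deviation (SD) over 3 libraries and each SE is that of a log2 fold change.

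Differences were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) in 1 model with a mean for each of the 4 groups, so that all 12 libraries share the estimate of spread. The 5 contrasts were starvation in control cells, starvation in OGDH-depleted cells, OGDH loss with glucose, OGDH loss without glucose, and the interaction, which is the difference between the starvation responses. P-values were adjusted by the Benjamini-Hochberg method over the tested genes of a contrast, with a threshold of 0.05. The median SE of a log2 fold change was 0.22 for starvation in control cells and 0.31 for the interaction.

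The design, most alternatives and 34 gene lists were fixed before the data were examined. A list was tested where at least 5 members were measured, which held for 33 lists; of the 10 blood cell markers, 3 were measured and that list was not tested. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. The list calls numbered 17 for starvation in control cells, 12 for OGDH loss with glucose, 5 for starvation in OGDH-depleted cells, 16 for OGDH loss without glucose and 14 for the interaction. Of these, 12, 6, 4, 10 and 13 also passed with an estimated correlation. A preset this low can make p-values too small where the members of a list vary together. The size of the smallest list p-values is therefore not a measure of strength.

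Beside each count of list members past the threshold over all genes, the count adjusted over the list alone is given where it differs; where it is not given it was the same.

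Genes were named by a rule fixed in advance. It takes OGDH; the 5 largest increases and 5 largest decreases past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the 2 groups' libraries (no overlap was asked of the interaction); the 3 members with the smallest p in each of the 5 lists with the smallest p; and a few fixed genes of the glucose and 2-oxoglutarate pathways. Genes named outside the rule are said to be so, and some genes that the rule takes are not reported here. Where a group lay at or near 0 counts, levels are given in place of a fold.

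Replicates were compared within groups. The chi-square per degree of freedom between replicate pairs was 3.91 to 160, and correlations of log2 CPM were 0.974 to 0.994, so no library repeats another. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

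The test was tried on simulated counts for the 18526 genes with 200 genes changed. For starvation in control cells it recovered 70% of 2-fold and 99% of 4-fold changes, with 6.11% of calls false. For the interaction it recovered 29% and 85%, with 5.79% false. In both, the list made of changed genes was called, and none of 30 lists of unchanged genes was. The simulated genes were drawn independently, so this does not check the list p-values where genes vary together. When a GC-dependent tilt that differed between replicates was added to the simulated libraries, the same test recovered 0% of 2-fold and 42% of 4-fold changes for starvation in control cells. With a GC offset it recovered 59% and 93% of them, with 6.17% of calls false. The tilt was added to a spread estimated from the real libraries, which already holds their own GC-related differences. It was the same for equal replicate numbers and followed GC content, which the offset removes by construction. These shares therefore do not measure the power of either fit on these data. Changes of 2-fold were missed in each simulation, so genes not called are weak evidence of no change.

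Alternatives covered other scalings (DESeq2 size factors, upper quartile), DESeq2 1.42.0, other filters, a fit of the compared groups only, the replicate number as a block, each library left out in turn, and a test against a 1.5-fold change. A GC offset for each library, a GC slope covariate, removal of the mitochondrial genes, and removal of 3 outlying libraries were added after seeing the data. Coordinates are from GENCODE release 29 on hg38, matched by gene name.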

Results

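RNA was sequenced from A375 cells, an established human melanoma line, in 4 groups of 3 libraries. Control cells and cells depleted of OGDH were each grown with glucose or starved of glucose for 5 h before collection. OGDH encodes the E1 subunit of the 2-oxoglutarate dehydrogenase complex, an enzyme of the tricarboxylic acid cycle. The sample titles call the depleted cells KO, whereas the series text speaks of knockdown, and "OGDH-depleted" is used here for both. Libraries held 21556273 to 25546615 counted fragments. Values with ± are mean CPM and SD of n = 3 libraries.

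Mitochondrially encoded transcripts took a share of the counts that differed between replicates. The share was 4.97%, 14.6% and 6.35% in control replicates 1, 2 and 3, and 14.4%, 13.2% and 4.11% in the starved control replicates. It was 6.25%, 6.98% and 5.16% in OGDH-depleted cells with glucose and 3.06%, 5.12% and 9.71% in starved OGDH-depleted cells. Of the 13 mitochondrially encoded respiratory chain mRNAs, 0 passed the edgeR test for starvation in control cells, 0 had an unadjusted p under 0.05 and 0 were called by DESeq2 (median log2 fold change 0.33, adjusted p = 0.76 for the list). For OGDH loss without glucose the list stood at a median of -1.004 (adjusted p = 0.14), with 1 of 13 lower by edgeR, 4 at an unadjusted p under 0.05 and 4 called by DESeq2. With glucose it stood at -0.61 (adjusted p = 0.15), with 0 by each of the 3. Without the 3 outlying libraries, chosen after seeing the data, the mitochondrially encoded respiratory chain list was called for starvation in control cells (median 1.68, 12 of 13 higher) and for OGDH loss without glucose (median -2.12, 13 of 13 lower), so its call depended on which libraries were kept. Control replicate 2, starved control replicate 3 and starved OGDH-depleted replicate 3 stood farthest from the other libraries of their groups.

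OGDH itself (chromosome 7, 44606572 to 44709066, hg38) was measured first because it checks the labels. Its level was 154 ± 11.9 CPM in control cells and 39.8 ± 4.68 CPM in OGDH-depleted cells with glucose, which is 25.8% of control (log2 fold change -1.96, SE 0.10, adjusted p = 8.6e-06). Without glucose it was 131 ± 2.01 CPM in control and 32.8 ± 0.904 CPM in depleted cells (-1.99, SE 0.10, adjusted p = 3.5e-07). All 6 depleted libraries lay between 32.3 and 45.1 CPM and all 6 control libraries between 129 and 166 CPM. Starvation shifted OGDH by -0.24 in control cells (adjusted p = 0.081) and -0.28 in depleted cells (adjusted p = 0.12), neither past the threshold. In control cells that value passed with upper-quartile scaling (-0.30, adjusted p = 0.037), with the stricter filter (adjusted p = 0.048) and without control replicate 2 (adjusted p = 0.036).

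**Figure D1:**
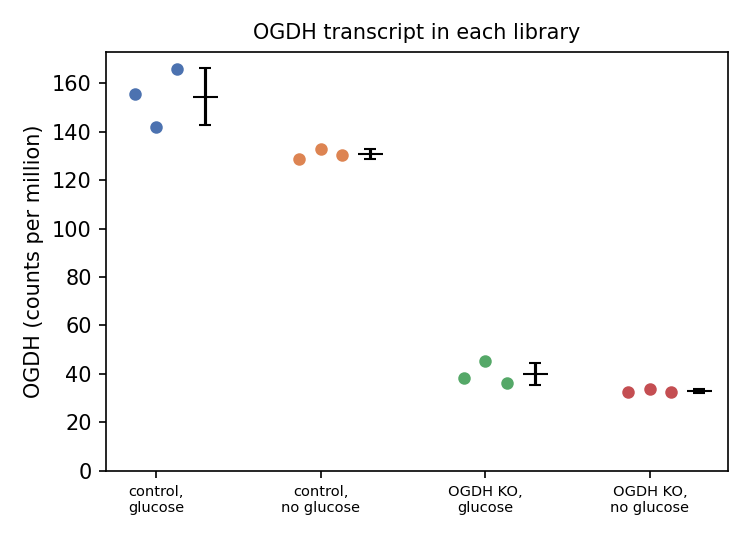
OGDH transcript in CPM (vertical axis, from 0) in each of the 12 libraries, by group; points are libraries and the bar beside them is the mean with its SD (n = 3). The 6 OGDH-depleted libraries sit at 45.1 CPM or lower and the 6 control libraries at 129 CPM or higher.

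Starvation of control cells asked how 5 h without glucose changes expression where OGDH is intact. Chaperones of the endoplasmic reticulum (ER) rose: HSPA5, the main ER chaperone, went from 798 ± 42.7 to 11446 ± 686 CPM (14.3-fold, adjusted p = 2.4e-09). DDIT3, a stress-induced transcription factor, went from 13.2 ± 1.93 to 171 ± 24.0 CPM, and FOS, an immediate early transcription factor, from 13.6 ± 1.87 to 402 ± 40.0 CPM. HMOX1, the enzyme that breaks down heme, went from 14.8 ± 4.41 to 3543 ± 954 CPM. PLK1, a mitotic kinase, went from 232 ± 13.6 to 81.7 ± 3.11 CPM.

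By list, all 20 immediate early genes rose in starved control cells (median log2 fold change 2.29, list adjusted p = 2.7e-53 by camera), among them FOSB (4.21, SE 0.12) and ZFP36 (3.98, SE 0.15), whose product destabilises mRNAs. In the ER chaperone and unfolded protein response list 20 of 21 rose (median 1.96, adjusted p = 6.0e-53), with HYOU1 at 2.39 (SE 0.09) and HERPUD1 at 3.59 (SE 0.13). Of the integrated stress response list 14 of 16 rose and 1 fell (median 2.55, adjusted p = 3.8e-28), including PPP1R15A (3.20, SE 0.14), a regulator of eIF2-alpha phosphatase, and CTH (3.07, SE 0.14), an enzyme of cysteine synthesis. All 12 cytosolic heat shock genes rose (median 1.17, adjusted p = 6.8e-23), with BAG3 at 2.62 (SE 0.11) and DNAJB1 at 3.86 (SE 0.17). Amino acid synthesis, transport and tRNA charging genes rose in 23 of 28 cases (24 adjusted over the list alone; median 0.94, adjusted p = 6.1e-13), including SLC1A4 (2.36, SE 0.11), MTHFD2 (1.29, SE 0.08), WARS1 (1.73, SE 0.11) and ASNS (1.92, SE 0.18).

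Cell cycle genes moved the other way. Of the G2/M list 18 of 21 fell (20 adjusted over the list alone; median -1.13, adjusted p = 7.9e-13), and of the G1/S list 15 of 22 fell and 2 rose (16 and 2 adjusted over the list alone; median -0.68, adjusted p = 8.2e-05). Interferon response genes fell in 9 of 18 cases (10 adjusted over the list alone; median -0.54, adjusted p = 0.00012). Lysosome and autophagy genes rose in 16 of 33 cases (18 adjusted over the list alone; median 0.42, adjusted p = 1.2e-05), and protein glycosylation genes in 13 of 20, with 1 lower (13 and 1 adjusted over the list alone; median 0.50, adjusted p = 1.2e-05). Hypoxia-inducible factor targets rose in 7 of 18 cases with 1 lower (8 and 1 adjusted over the list alone; median 0.40, adjusted p = 0.00030), and FOXO and fasting genes in 9 of 16 with 5 lower (10 and 5 adjusted over the list alone; median 0.92, adjusted p = 0.0089).

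TXNIP, a glucose-induced arrestin that restrains glucose uptake, fell from 10.9 ± 0.232 to 7.26 ± 0.763 CPM in starved control cells (-0.58, SE 0.13, adjusted p = 0.0043). The list of glucose-sensing MondoA targets that holds it nevertheless had 4 of 7 members higher and 1 lower (median 1.003, adjusted p = 0.013; adjusted p = 0.051 with an estimated correlation). The 4 higher ones, named after their values were seen, were ARRDC3 (1.003), HBP1 (1.15), KLF10 (1.86) and KLF11 (1.15), the last 3 of which encode transcriptional repressors. ARRDC4 stood at 0.28 (SE 0.13, adjusted p = 0.13; 0.042 without the 3 outlying libraries). The glucose transporter SLC2A1 stood at 0.45 (SE 0.32, adjusted p = 0.31) but passed with a GC slope covariate chosen after seeing the data and made from the same libraries (0.76, adjusted p = 5.1e-09). The glycolysis list, with 4 of 23 higher and 3 lower, was not called (adjusted p = 0.38).

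Other list calls for starvation in control cells were lost when the correlation between genes was estimated. NRF2 and oxidative stress genes rose in 10 of 18 cases with 1 lower (11 and 1 adjusted over the list alone; adjusted p = 6.2e-07; adjusted p = 0.051 with an estimated correlation). MAPK output genes had 6 of 16 higher and 4 lower (7 and 4 adjusted over the list alone; adjusted p = 0.023; adjusted p = 0.055 with an estimated correlation). NF-kB and cytokine genes had 11 of 22 higher and 2 lower (adjusted p = 0.029; adjusted p = 0.32 with an estimated correlation and 0.087 without the 3 outlying libraries). Transcripts kept in the nucleus had 4 of 6 higher (adjusted p = 0.046; adjusted p = 0.10 with an estimated correlation, 0.18 with a GC offset and 0.12 with the GC slope covariate).

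Besides HMOX1, some genes that were almost silent with glucose rose in starved control cells. HSPA6, an inducible heat shock gene, went from 0.726 ± 0.258 to 353 ± 131 CPM. XIRP1, a muscle actin-binding protein, stood at 0.0800 ± 0.104 and then 37.8 ± 4.02 CPM, and KRT16, an epithelial keratin, at 0.0536 ± 0.0603 and then 20.04 ± 6.82 CPM. HSPA1A went from 0.809 ± 0.208 to 42.8 ± 7.47 CPM, a level that is uncertain because fragments shared with HSPA1B were not counted. The largest decreases were in E2F2 (-3.24, SE 0.22), a cell cycle transcription factor, the chemokine CCL2 (-3.24, SE 0.16), DIXDC1 (-3.17, SE 0.16), ZNF488 (-2.97, SE 0.20) and MEOX2 (-2.96, SE 0.18).

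Across all 18526 genes the edgeR test called 6400 for starvation in control cells, 3151 higher and 3249 lower, with 1438 higher and 1322 lower by at least 2-fold. The count was 2287 when a change above 1.5-fold was required. It was 11364 without the 3 outlying libraries, a removal chosen after seeing the data that lowers the spread by construction.

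**Figure D2:**
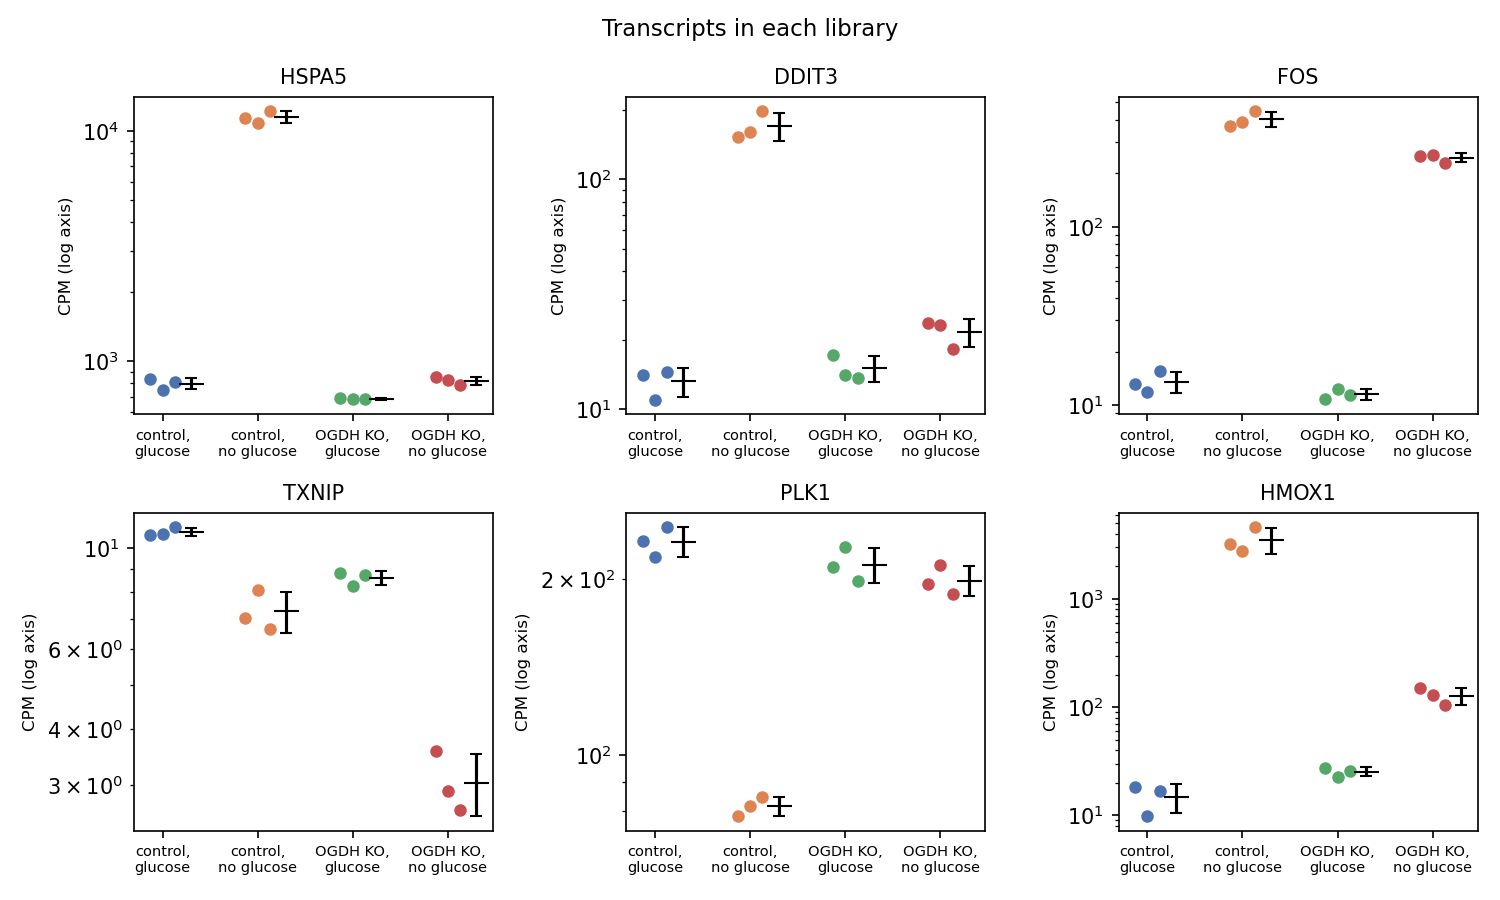
HSPA5, DDIT3, FOS, TXNIP, PLK1 and HMOX1 in CPM (log axes) in each library, by group, with the mean and SD (n = 3) beside the points. HSPA5 stands at 11446 CPM in starved control cells and at 821 CPM in starved OGDH-depleted cells, while FOS stands at 402 and 245 CPM.

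Starvation of OGDH-depleted cells asked the same question where OGDH is low. FOS went from 11.5 ± 0.787 to 245 ± 13.6 CPM (4.41, SE 0.13, adjusted p = 2.2e-08) and EGR1, another immediate early factor, from 163 ± 30.3 to 2606 ± 1064 CPM (3.997, SE 0.43). HSPA5 stood at 685 ± 6.75 CPM with glucose and 821 ± 32.8 CPM without (0.26, SE 0.09, adjusted p = 0.12), and DDIT3 at 15.1 ± 1.95 and 21.7 ± 2.97 CPM (0.53, SE 0.16, adjusted p = 0.068). Both passed with DESeq2, HSPA5 at an adjusted p of 0.012 and DDIT3 at 0.033, and DDIT3 also with a GC offset (adjusted p = 0.021). Both passed too with the GC slope covariate (HSPA5 0.34, adjusted p = 0.00017; DDIT3 0.74, adjusted p = 1.8e-05) and without the 3 outlying libraries (adjusted p = 0.019 and 0.0015), so a small rise of these 2 genes in depleted cells is not ruled out. TXNIP fell from 8.60 ± 0.299 to 3.04 ± 0.474 CPM (-1.49, SE 0.13, adjusted p = 9.1e-05), and ARRDC4 fell by 0.57 (SE 0.14, adjusted p = 0.028), a call lost without any 1 of the 6 libraries compared (adjusted p = 0.052 to 0.12). The MondoA list that holds both had 3 of 7 members higher and 2 lower (4 and 2 adjusted over the list alone; median 0.48, adjusted p = 0.99).

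Of the immediate early genes 14 of 20 rose in starved OGDH-depleted cells and 1 fell (14 and 1 adjusted over the list alone; median 1.59, adjusted p = 4.4e-60), including FOSB (2.72, SE 0.11) and ZFP36 (2.51, SE 0.14). The gene that fell, named after its value was seen, was BTG2 (-0.90), an antiproliferative gene. Cytosolic heat shock genes rose in 7 of 12 cases (9 adjusted over the list alone; median 0.64, adjusted p = 1.5e-17), with HSPA1A at 3.01 (SE 0.19), DNAJB1 at 2.19 (SE 0.15) and BAG3 at 0.84 (SE 0.10), and HSPA6 rose by 3.95 (SE 0.33). NF-kB and cytokine genes rose in 11 of 22 cases (12 adjusted over the list alone; median 0.59, adjusted p = 1.2e-14), among them IL6 (2.16, SE 0.18), CXCL1 (1.20, SE 0.11) and TNFAIP3 (1.497, SE 0.10), an inhibitor of NF-kB signalling. Hypoxia-inducible factor targets rose in 3 of 18 cases with 1 lower (10 and 2 adjusted over the list alone; median 0.42, adjusted p = 0.00064), the 3 being KDM3A (0.77), ANKRD37 (1.01) and STC1 (0.79). The call of STC1 was lost without any 1 of 5 libraries, all but starved OGDH-depleted replicate 1 (adjusted p = 0.063 to 0.097), and that of ANKRD37 with a GC offset (adjusted p = 0.070). FOXO and fasting genes rose in 5 of 16 cases (5 adjusted over the list alone; median 0.06, mean 0.37, adjusted p = 0.0073; adjusted p = 0.053 with an estimated correlation), with BCL6 at 0.97, FBXO32 at 0.91 and CCNG2 at 1.14.

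Several lists that moved in starved control cells were not called in starved OGDH-depleted cells. The ER chaperone list had a median of 0.12 (adjusted p = 0.51), with 0 of 21 members called by edgeR (1 higher and 2 lower adjusted over the list alone), 5 at an unadjusted p under 0.05 and 5 called by DESeq2. The amino acid list had a median of -0.03 (adjusted p = 0.85), with 0 of 28 called by edgeR, 2 at an unadjusted p under 0.05 and 0 called by DESeq2. The G2/M list had a median of 0.19 (adjusted p = 0.28), with 0 of 21 called by edgeR, 2 at an unadjusted p under 0.05 and 0 called by DESeq2. In the integrated stress response list 2 of 16 rose, ATF3 (1.61) and PPP1R15A (1.28), both named after their values were seen (3 higher and 1 lower adjusted over the list alone); the median was -0.13, the mean 0.03 and the adjusted p 0.54. With a GC offset that list was called (4 higher and 1 lower, adjusted p = 0.023), although its median was 0.0016. ASNS, the asparagine synthetase, stood at 0.18 (SE 0.17, adjusted p = 0.53) and SLC2A1 at -0.06 (SE 0.32, adjusted p = 0.93). With the GC slope covariate, chosen after seeing the data, SLC2A1 turned to 0.47 (adjusted p = 3.5e-05 by edgeR).

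The largest decreases in starved OGDH-depleted cells were in mitochondrial tRNA transcripts, with MT-TH going from 15.2 ± 3.73 to 0.725 ± 0.317 CPM, MT-TR from 6.87 ± 1.21 to 0.709 ± 0.226 CPM, MT-TC from 46.9 ± 12.3 to 5.89 ± 0.818 CPM and MT-TN from 14.9 ± 1.35 to 1.95 ± 0.327 CPM. RHBDL1, a rhomboid protease, fell by 2.44 (SE 0.38). Transcripts this short are poorly recovered by standard libraries, so their levels depend on the fragments retained. The edgeR test called 1330 genes, 448 higher and 882 lower, with 176 higher and 419 lower by at least 2-fold. That count was 2031 with DESeq2 (40.7% higher against 33.7%) and 220 against a 1.5-fold change. It was 629, 631 and 639 without OGDH-depleted replicate 1, 2 or 3, and 583 and 607 without starved OGDH-depleted replicate 2 or 3.

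OGDH loss with glucose asked what depletion changes in fed cells. STC2, a secreted stress-response glycoprotein, went from 38.7 ± 4.26 to 107 ± 3.26 CPM (1.47, SE 0.13, adjusted p = 0.00021) and SLC1A4, a neutral amino acid transporter, from 11.6 ± 0.867 to 31.4 ± 0.622 CPM (1.44, SE 0.10, adjusted p = 6.2e-05). The chemokine CXCL1 went from 90.5 ± 1.11 to 25.2 ± 3.40 CPM (-1.85, SE 0.11, adjusted p = 2.3e-05) and CCL2 from 21.3 ± 0.652 to 4.69 ± 0.782 CPM (-2.19, SE 0.15, adjusted p = 4.8e-05). The replicative helicase subunit MCM3 fell from 206 ± 19.9 to 136 ± 2.06 CPM.

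In fed OGDH-depleted cells 9 of 16 integrated stress response genes rose (11 adjusted over the list alone; median 0.74, adjusted p = 3.4e-25), including CEBPG (0.76, SE 0.10) and INHBE, which went from 0.696 ± 0.355 to 5.11 ± 0.164 CPM. Amino acid genes rose in 7 of 28 cases (17 adjusted over the list alone; median 0.52, adjusted p = 5.7e-20), with MTHFD2 at 0.90 (SE 0.08) and PSAT1, a serine synthesis enzyme, at 0.84 (SE 0.11). NF-kB and cytokine genes fell in 8 of 22 cases and rose in 2 (10 and 2 adjusted over the list alone; median -0.29, adjusted p = 1.1e-09), CXCL3 among those that fell (-1.17, SE 0.14). G1/S genes fell in 9 of 22 cases (12 adjusted over the list alone; median -0.37, adjusted p = 2.4e-08), with GINS2 at -0.61 (SE 0.10) and CDC6 at -0.44 (SE 0.08). Cholesterol synthesis genes fell in 5 of 23 cases (9 adjusted over the list alone; median -0.27, adjusted p = 8.1e-06), with INSIG1 at -0.74 (SE 0.08) and STARD4 at -0.83 (SE 0.15). Calls were lost for CDC6 without any 1 of 5 libraries, all but control replicate 2 (adjusted p = 0.058 to 0.095), for GINS2 without OGDH-depleted replicate 1 or 3 (0.053 and 0.059) and for STARD4 without replicate 1 or 2 (0.079 and 0.080). These 3 and MCM3 were also lost with only the compared groups in the fit (adjusted p = 0.050 to 0.085). MAPK output genes rose in 3 of 16 cases (6 adjusted over the list alone; median 0.06, mean 0.17, adjusted p = 0.0031).

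The other list calls for OGDH loss with glucose were lost when the correlation between genes was estimated. The G2/M list had a median of -0.23 and 0 of 21 members called by edgeR, 5 at an unadjusted p under 0.05 and 2 called by DESeq2 (adjusted p = 0.0031; adjusted p = 0.28 with an estimated correlation and 0.061 with fry). NRF2 genes had 1 of 18 higher (4 adjusted over the list alone; adjusted p = 0.0031; adjusted p = 0.23 with an estimated correlation). Immediate early genes had 5 of 20 higher and 1 lower (adjusted p = 0.0037; adjusted p = 0.18 with an estimated correlation), whose median of 0.11 became -0.05 with a GC offset (adjusted p = 0.30). Fatty acid synthesis genes had 3 of 13 lower (4 adjusted over the list alone; adjusted p = 0.012; adjusted p = 0.071 with an estimated correlation). Lysosome genes had 2 of 33 higher (adjusted p = 0.026; adjusted p = 0.17 with an estimated correlation). Matrix and adhesion genes had 1 of 18 higher (adjusted p = 0.043; adjusted p = 0.18 with an estimated correlation and 0.11 with a GC offset). The ER chaperone list was not called (median -0.07, adjusted p = 0.68), although XBP1 (0.55) and HERPUD1 (0.53) rose, both named here after their values were seen (2 higher and 3 lower adjusted over the list alone).

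The largest increases with OGDH loss in glucose were in INHBE, ANKRD1 (2.83, SE 0.16), ADM2 (2.42, SE 0.26), CHAC1 (2.31, SE 0.35), a glutathione-degrading enzyme, and S1PR1 (1.92, SE 0.13), a lipid receptor. Besides OGDH and the chemokines, the largest decreases were in SHISA2 (-1.73, SE 0.17) and ADAMTS15 (-1.67, SE 0.29), whose call was lost without OGDH-depleted replicate 1 or 2 (adjusted p = 0.068 and 0.067). The partners of OGDH in its complex stood at -0.03 for DLST (SE 0.17, adjusted p = 0.95; -0.18 and 0.021 with the GC slope covariate) and -0.12 for DLD (SE 0.12, adjusted p = 0.70), the paralog OGDHL at -0.85 (SE 0.32, adjusted p = 0.21; 0.041 with a GC offset and 0.020 with the GC slope covariate) from a level of 0.754 ± 0.245 CPM, and GLUD1, the glutamate dehydrogenase, at -0.16 (SE 0.10, adjusted p = 0.49). The test called 563 genes, 294 higher and 269 lower, with 67 higher and 77 lower by at least 2-fold. That count was 1172 with DESeq2, 215 with only the compared groups in the fit and 28 (64.3% higher against 52.2%) against a 1.5-fold change. It was 288 and 238 without control replicate 1 or 3, and 172, 193 and 224 without OGDH-depleted replicate 1, 2 or 3.

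OGDH loss without glucose compared the starved groups. HSPA5 was 821 ± 32.8 CPM in OGDH-depleted and 11446 ± 686 CPM in control cells (-3.80, SE 0.11, adjusted p = 8.4e-09), and DDIT3 was 21.7 ± 2.97 against 171 ± 24.0 CPM (-2.98, SE 0.16, adjusted p = 4.6e-07). HMOX1 was 128 ± 23.0 against 3543 ± 954 CPM (-4.79, SE 0.28). PLK1 was 199 ± 11.5 against 81.7 ± 3.11 CPM (1.29, SE 0.09, adjusted p = 2.2e-06), and the mitotic cyclin CCNB1 was 135 ± 7.84 against 58.6 ± 3.77 CPM.

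Between the starved groups, 19 of 21 ER chaperone genes were lower in OGDH-depleted cells (median -1.97, adjusted p = 1.3e-66), with HYOU1 at -2.59 (SE 0.09) and DNAJB11 at -2.13 (SE 0.08). Integrated stress response genes were lower in 12 of 16 cases and higher in 1 (median -1.22, adjusted p = 1.1e-12), with CTH at -2.05 (SE 0.13) and CEBPG at -1.45 (SE 0.10). Of the heat shock list 11 of 12 were lower (median -0.93, adjusted p = 2.5e-12), with BAG3 at -2.01 (SE 0.11), HSPA1A at -2.47 (SE 0.16) and HSPH1 at -1.59 (SE 0.13). Immediate early genes were lower in 13 of 20 cases and higher in 1 (median -0.75, adjusted p = 2.3e-10), with BTG2 at -1.88 (SE 0.09), KLF6 at -1.87 (SE 0.12) and DUSP1, a MAPK phosphatase, at -2.78 (SE 0.19). G2/M genes were higher in 18 of 21 cases (19 adjusted over the list alone; median 0.99, adjusted p = 2.7e-14), with KIF20A at 1.65 (SE 0.13), and interferon genes in 9 of 18 (10 adjusted over the list alone; median 0.76, adjusted p = 8.7e-05). Amino acid genes were lower in 15 of 28 cases (18 adjusted over the list alone; median -0.44, adjusted p = 0.00018), glycosylation genes in 11 of 20 with 3 higher (11 and 3 adjusted over the list alone; median -0.39, adjusted p = 0.00040), MondoA targets in 5 of 7 (6 adjusted over the list alone; median -0.82, adjusted p = 0.00060) and nuclear transcripts in 5 of 6 (5 lower and 1 higher adjusted over the list alone; median -0.72, adjusted p = 0.00061).

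For 6 further lists the call between the starved groups was lost with an estimated correlation. NRF2 genes had 10 of 18 lower and 1 higher (11 and 1 adjusted over the list alone; adjusted p = 5.8e-05; adjusted p = 0.095 with an estimated correlation) and cholesterol synthesis genes 8 of 23 lower (median -0.21, adjusted p = 0.0081; adjusted p = 0.073 with an estimated correlation; median 0.05 without the 3 outlying libraries). Lysosome genes had 9 of 33 lower and 2 higher (adjusted p = 0.017; adjusted p = 0.092 with an estimated correlation). Hypoxia-inducible factor targets had 5 of 18 lower (adjusted p = 0.029; adjusted p = 0.073 with an estimated correlation). Epithelial markers had 2 of 5 lower (adjusted p = 0.029; adjusted p = 0.19 with an estimated correlation and 0.075 with a GC offset). Their median of -0.59 became -0.08 without the 3 outlying libraries (adjusted p = 0.23). FOXO genes had 7 of 16 lower and 4 higher (8 and 5 adjusted over the list alone; adjusted p = 0.047; adjusted p = 0.095 with an estimated correlation and 0.086 with a GC offset).

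The genes most above control in starved OGDH-depleted cells were SORBS2-AS1 (2.62, SE 0.24), an antisense RNA counted without strand, MEOX2 (2.48, SE 0.17), B4GAT1 (2.48, SE 0.31), DIXDC1 (2.48, SE 0.16) and ZMYM3 (2.40, SE 0.11). Those most below were KRT16, at 0.177 ± 0.119 against 20.04 ± 6.82 CPM, XIRP1, at 0.411 ± 0.122 against 37.8 ± 4.02 CPM, ZNF469 (-5.06, SE 0.23), HSPA6 (-4.81, SE 0.30) and HMOX1. GLUD1 was lower by the edgeR test (-0.51, SE 0.10, adjusted p = 0.0030), while DLST stood at -0.10 (SE 0.17, adjusted p = 0.71), DLD at 0.12 (SE 0.13, adjusted p = 0.51) and OGDHL at -0.23 (SE 0.35, adjusted p = 0.67). With the GC slope covariate DLST (-0.14, adjusted p = 0.023) and DLD (0.15, adjusted p = 0.0068) passed as well. The test called 5310 genes, 2531 higher and 2779 lower, with 843 higher and 1337 lower by at least 2-fold. The count was 1653 against a 1.5-fold change.

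**Figure D3:**
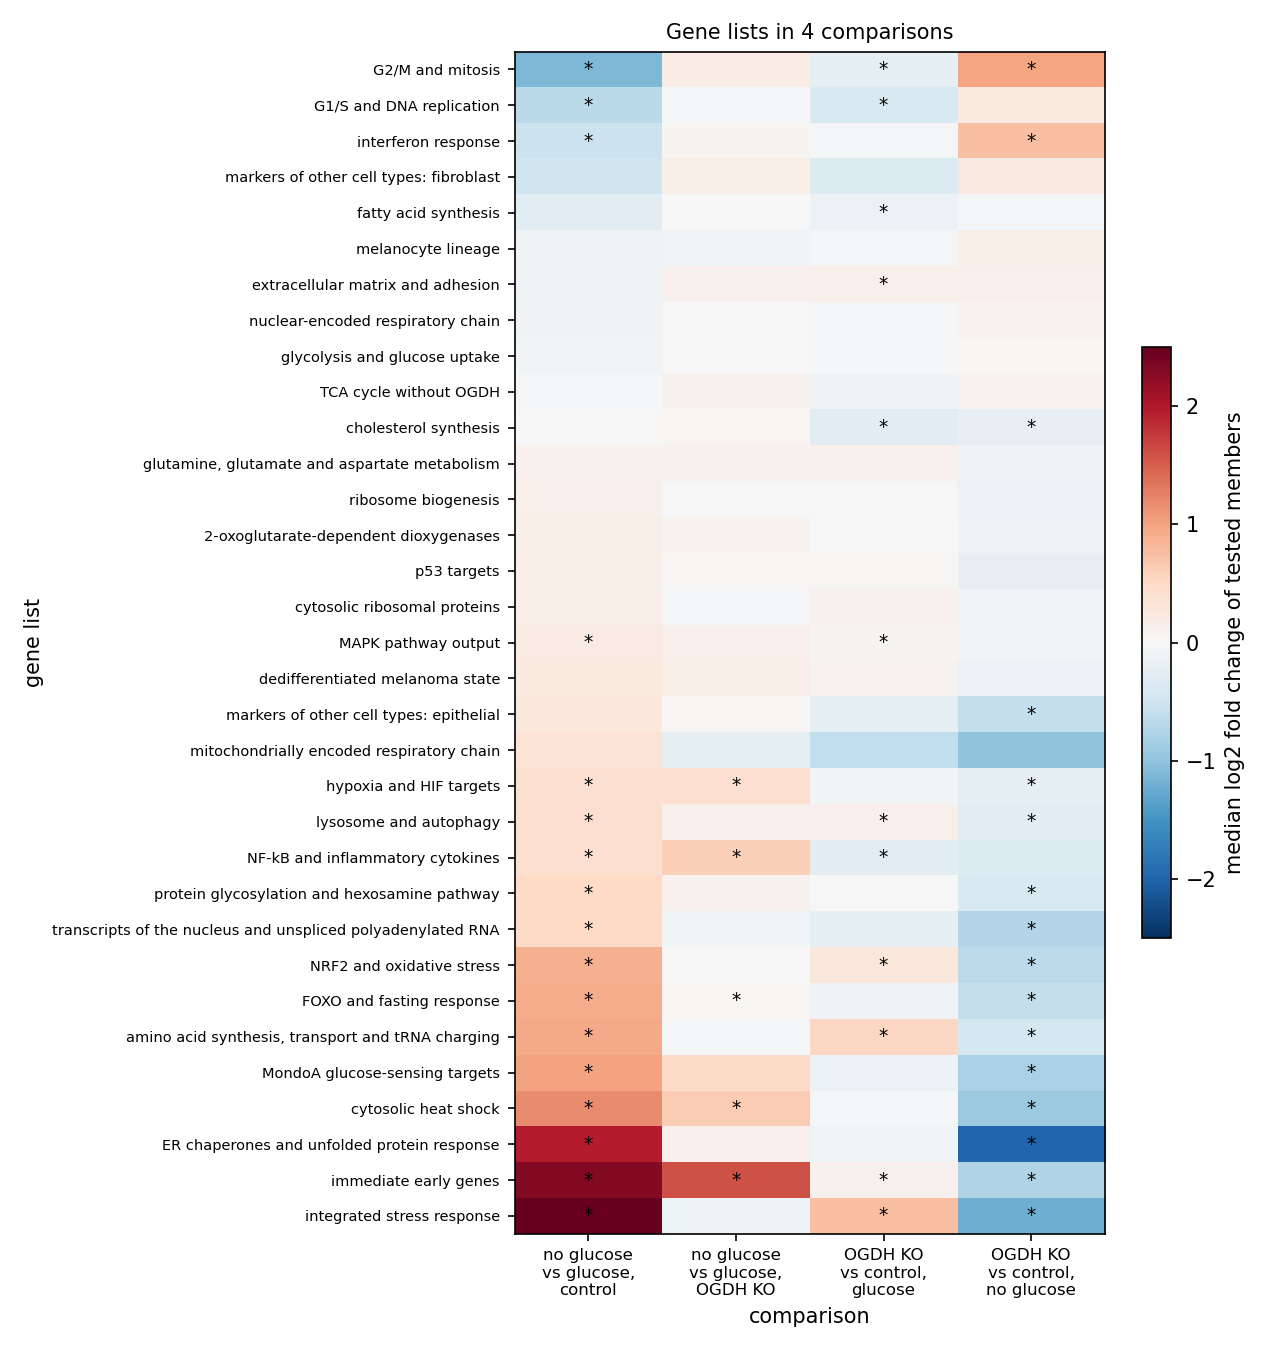
Median log2 fold change of each tested gene list (rows of the map) in 4 comparisons (columns), as colour; an asterisk marks an adjusted p under 0.05 by camera. The ER chaperone list stands at 1.96 for starvation in control cells, 0.12 for starvation in OGDH-depleted cells and -1.97 for OGDH loss without glucose.

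The interaction asked whether the starvation response differed with OGDH status; a negative value means a smaller rise, or a larger fall, in OGDH-depleted cells. The HSPA5 response was smaller in depleted cells (-3.58, SE 0.14, adjusted p = 3.2e-07), as were those of DDIT3 (-3.17, SE 0.22, adjusted p = 6.6e-06) and HMOX1 (-5.56, SE 0.36, adjusted p = 3.8e-06). PLK1 (1.42, SE 0.13, adjusted p = 3.0e-05), KIF20A (2.06, SE 0.17) and AURKA (1.32, SE 0.12), all mitotic kinases or motors, fell in control cells and had a positive interaction. CCL2, which fell from 21.3 to 2.26 CPM in control cells, rose from 4.69 to 8.42 CPM in depleted cells (interaction 4.08, SE 0.22, adjusted p = 1.3e-06).

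In the interaction, 19 of 21 ER chaperone genes had a lower response in depleted cells (median -1.87, adjusted p = 1.4e-58), with HYOU1 at -2.504 (SE 0.12) and XBP1, a transcription factor of the unfolded protein response, at -2.22 (SE 0.11). The same held for 14 of 16 integrated stress response genes (14 lower and 1 higher adjusted over the list alone; median -2.36, adjusted p = 1.6e-31), with CTH at -2.91 (SE 0.19) and CEBPG at -2.22 (SE 0.15), and for 19 of 28 amino acid genes (25 adjusted over the list alone; median -1.16, adjusted p = 2.4e-15), with SLC1A4 at -2.55 (SE 0.15), MTHFD2 at -1.27 (SE 0.11) and WARS1 at -1.54 (SE 0.15). Part of the interaction of these lists came from levels already raised in fed depleted cells. With OGDH loss the integrated stress response median was 0.74 with glucose and -1.22 without. The amino acid median was 0.52 with glucose and -0.44 without. Immediate early genes were lower in 11 of 20 cases (13 adjusted over the list alone; median -0.80, adjusted p = 1.3e-13), among them KLF4 (-2.07, SE 0.15), KLF2 (-1.96, SE 0.17) and KLF6 (-1.73, SE 0.16), which encode Krüppel-like factors. Heat shock genes were lower in 9 of 12 (median -0.90, adjusted p = 1.2e-08) and NRF2 genes in 9 of 18 with 1 higher (11 and 1 adjusted over the list alone; median -0.93, adjusted p = 5.0e-08). G2/M genes were higher in 19 of 21 cases (median 1.32, adjusted p = 1.2e-17), interferon genes in 9 of 18 (median 0.81, adjusted p = 2.9e-05) and G1/S genes in 8 of 22 with 2 lower (9 and 2 adjusted over the list alone; median 0.58, adjusted p = 0.00026).

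Further lists were called in the interaction by camera. Glycosylation genes had 8 of 20 lower and 1 higher (11 and 1 adjusted over the list alone, median -0.38, adjusted p = 8.7e-05). Lysosome genes had 6 of 33 lower (6 adjusted over the list alone, median -0.23, adjusted p = 0.00050). MondoA targets had 4 of 7 lower (median -0.68, adjusted p = 0.0073). Nuclear transcripts had 3 of 6 lower (4 adjusted over the list alone, median -0.67, adjusted p = 0.012). The call of nuclear transcripts was lost with the GC slope covariate (adjusted p = 0.053). MAPK output genes had 4 of 16 lower and 2 higher (adjusted p = 0.032; adjusted p = 0.069 with an estimated correlation). Among the largest interactions, SOX5 (3.54, SE 0.32), DIXDC1 (3.48, SE 0.21), TNFRSF19 (2.89, SE 0.15) and ADORA1 (2.85, SE 0.22) were positive, and ZNF469 (-5.32, SE 0.31) and PRR9 (-5.66, SE 0.59) negative. PRR9, KRT16 and XIRP1 lay under 1 CPM in every group but starved control cells, where PRR9 reached 7.08 ± 1.41 CPM. The interaction calls of KRT16 and XIRP1 were lost without OGDH-depleted replicate 3 (adjusted p = 0.073 and 0.058). OGDH had an interaction of -0.04 (SE 0.14, adjusted p = 0.90). The test called 3196 genes, 1537 higher and 1659 lower, with 819 and 1001 by at least 2-fold. The count was 1080 against a 1.5-fold change and 5122 with a GC offset for each library, which was added after seeing the data.

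**Figure D4:**
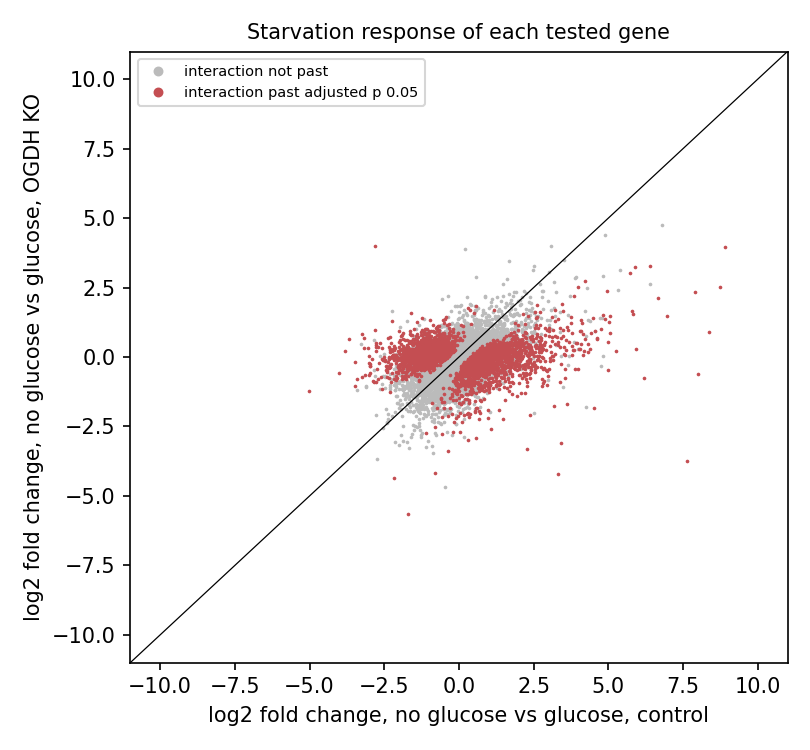
Log2 fold change with starvation of each tested gene in control cells (horizontal axis) and in OGDH-depleted cells (vertical axis), with the line of equal response; genes past the interaction threshold are in red. The red genes number 3196.

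Both starvation comparisons use separate libraries, so their overlap is not raised by shared controls. They do share the estimate of spread, so genes of low spread are more readily called in both. Independent lists are therefore a low baseline. The overlap was not counted with a GC offset, so a GC-related difference common to both comparisons is not excluded. Genes called in both numbered 805. Of these, 674 moved the same way, 288 up and 386 down, where independent lists would share 231 (76.2 up and 155 down). Another 131 moved in opposite ways, against 229 for independent lists. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.36. Of the 6400 genes called in control cells 2800 also passed the interaction, and 2720 of those had the smaller response in depleted cells. Of the 525 called in depleted cells alone, 202 passed the interaction. Choosing genes by their call in control cells, whose libraries also enter the interaction, favours a smaller response in depleted cells, so the 2720 are not a measure of how general that is.

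For OGDH loss, 371 genes were called both with and without glucose. Of these, 191 moved the same way (90 up and 101 down, against 80.5 for independent lists) and 180 in opposite ways (against 80.9), and log2 fold changes correlated at r = 0.05 across genes. The estimate of spread is shared here too, so an excess over independent lists does not by itself link the effects. CCL2 shows the opposite kind, lower with OGDH loss in glucose (-2.19) and higher without it (1.90, SE 0.16, adjusted p = 7.9e-06).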

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

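The tests of whether OGDH-depleted cells had lost their glucose, of whether their ER genes were already raised, and both tests of the mitochondrial share were chosen only after the result was seen, as was every alternative with a GC offset.

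The interaction brought up 3196 genes whose starvation response differed between control and OGDH-depleted cells, by a test of the difference itself. Of 100 splits of the 12 libraries into the same group sizes, 2 gave as many genes, the real one included, and the highest other split gave 4157 genes. Most splits mix fed with starved and control with depleted libraries, so those differences enter the spread and the share does not stand for data without an interaction. That split puts control replicate 2 together with starved control replicates 1 and 2, the 3 libraries with the highest mitochondrial share, so it points to a structure of the samples. With a GC offset for each library the real count was 5122, but no other split was counted that way, so it cannot be set against theirs.

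The differing lists, by median interaction on the log2 scale, were the integrated stress response at -2.36, ER chaperones at -1.87, amino acid genes at -1.16, NRF2 genes at -0.93, heat shock genes at -0.90, immediate early genes at -0.80, MondoA targets at -0.68, nuclear transcripts at -0.67, glycosylation genes at -0.38, MAPK output at -0.29 and lysosome genes at -0.23. Those with a positive median were G2/M genes at 1.32, interferon genes at 0.81 and G1/S genes at 0.58.

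Single genes that differed by the same test were, with a positive interaction, CCL2 (4.08), SOX5 (3.54), DIXDC1 (3.48), TNFRSF19 (2.89), ADORA1 (2.85), KIF20A (2.06), PLK1 (1.42) and AURKA (1.32). With a negative one they were PRR9 (-5.66), HMOX1 (-5.56), ZNF469 (-5.32), HSPA5 (-3.58), DDIT3 (-3.17), CTH (-2.91), SLC1A4 (-2.55), HYOU1 (-2.504), XBP1 (-2.22), CEBPG (-2.22), KLF4 (-2.07), KLF2 (-1.96), KLF6 (-1.73), WARS1 (-1.54) and MTHFD2 (-1.27). KRT16 and XIRP1 reached 20.04 and 37.8 CPM in starved control cells and had too few counts in the other groups for a fold.

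The ER chaperone list rose by a median of 1.96 with starvation in control cells and stood at 0.12 in OGDH-depleted cells, where fry, which does not compare the list with other genes, gave an adjusted p of 0.0034. GC-dependent differences between libraries do not account for this, since with a GC offset the median interaction was -1.83 and 20 of 21 members were lower (quartiles -2.42 and -1.20). Whether glucose was left in the starved OGDH-depleted cells stays open. TXNIP, named by the rule fixed in advance, fell there (-1.49), but it is 1 gene and became a test only after the result was seen. The MondoA list that holds it had 3 of 7 members higher and 2 lower (median 0.48, adjusted p = 0.99 by camera). In starved control cells that list also had 4 of 7 higher and 1 lower (median 1.003), so it cannot decide. The fed and starved depleted groups did differ, since 14 of 20 immediate early genes rose and 1 fell (median 1.59, adjusted p = 4.4e-60 by camera). That argues against libraries of the same condition under both labels. It does not show that glucose was removed, and the list was turned to for this question only after its rise was seen. The ER chaperone genes were not already at the starved level in fed depleted cells, where their median change with OGDH loss was -0.0717. A smaller ER stress response where OGDH is low, a different time course, other effects of the depletion procedure and a difference in cell density were not told apart by any test.

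The mitochondrial share differed between libraries of 1 group, from 4.97% to 14.6% among control libraries. GC-dependent recovery alone is argued against, because mitochondrial mRNAs shifted beyond nuclear transcripts of the same GC content by 1.39 (SD 0.322) in control replicate 2, by -2.09 (SD 0.404) in starved control replicate 3 and by 1.60 (SD 0.400) in starved depleted replicate 3, the smallest excess being 1.39. Whether the mitochondrial reads themselves distort the nuclear counts is open: without mitochondrial genes the AT-rich minus GC-rich difference spanned 1.19 on the log2 scale over the libraries, but their removal rescales all nuclear genes of a library alike and so decides nothing. The first axis of variation within groups held 57.3% of the variance and its loadings correlated with GC content at r = -0.67 across 12899 genes. RNA quality or handling that acts on both is open and was not tested, and no biological explanation was tested because the labels give no difference between replicates.

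For starvation in control cells (6400 genes) the highest of the other splits gave 4802 genes. That split again sets control replicate 2 and starved control replicates 1 and 2 against the rest. The real count with a GC offset was 8308, with no other split counted that way. The real split alone reached its count in each comparison of 6 libraries, 1 of 10 splits, and 10 splits are too few for a share under 0.05. The real counts were 563 for OGDH loss with glucose, 1330 for starvation in depleted cells and 5310 for OGDH loss without glucose, and the highest other split by edgeR gave 0 in each.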

How the results depend on the processing

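All main choices and most alternatives were fixed before the data were examined; the GC offset, the GC slope covariate, the removal of mitochondrial genes and that of 3 outlying libraries were chosen after seeing the data. The limit that picked the 3 libraries was set after their correlations were seen, and leaving out the least alike libraries, or fitting a covariate made from the same libraries, lowers the spread by construction, so the higher counts are not stronger evidence. Alternatives for normalized values were not run because the values are counts. OGDH kept its direction and its call under OGDH loss in each alternative (leave-one-out -2.05 to -1.89 with glucose, -2.01 to -1.96 without). Against a 1.5-fold change the counts were 2287 (starvation, control), 28 (OGDH loss, glucose), 220 (starvation, depleted), 1653 (OGDH loss, no glucose) and 1080 (interaction), a stricter question by construction. DESeq2 gave 1172 for OGDH loss with glucose and 2031 for starvation in depleted cells, and a fit of the compared groups alone gave 215 for the former; the cause was not tested. The GC offset gave 1455 for OGDH loss with glucose, 2047 for starvation in depleted cells and 5122 for the interaction. The GC slope covariate gave, in the order of the 1.5-fold counts, 10893, 4261, 4644 (47.9% higher against 33.7%), 10500 and 8545, and leaving out the 3 libraries gave 11364, 2021, 3313, 9874 and 8077. Leaving out 1 library at a time gave 5037 to 7527, 172 to 397, 583 to 1151, 4030 to 5388 and 2293 to 3319 in that order, from fewer samples. Genes changed at least 2-fold in the same direction numbered 244 for the starvation overlap and 39 for the OGDH overlap, from shorter lists. Reversed values were SLC2A1 for starvation in depleted cells under the GC slope covariate (0.47, adjusted p = 3.5e-05 by edgeR) and the glycolysis list in the interaction without the 3 libraries (median 0.47, adjusted p = 0.0057); neither was called before, and the cause was not tested. Of the other values, 1183 list results and 2547 named-gene results kept their direction and side of the threshold, 32 and 54 lost the call and 99 and 21 gained it.

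With the replicate number as a block the counts were 6032, 342, 1011, 4931 and 2759, and the overlaps in the same direction were 533 for starvation and 114 for OGDH loss. The block ended the list calls of nuclear transcripts for starvation in control cells (adjusted p = 0.052) and of matrix genes for OGDH loss with glucose (adjusted p = 0.052), and the call of ARRDC4 for starvation in depleted cells (adjusted p = 0.061); no other named gene or list call was lost. No pairing by number was seen: same-number correlations of the deviations within groups ran from -0.69 to 0.64, 7 of 18 were over 0.1, and 15 of 36 best matches were with the same number. The first axis held 57.3% of the variance within groups and followed GC content. A pairing could therefore have stayed hidden and is not excluded.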

Other observations

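The protocadherin test of shared reads was chosen only after the result was seen, and the gene families here were grouped by symbol after their values were seen.

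Among 19 families looked at, the clustered protocadherins, cell-surface adhesion proteins encoded in tandem arrays, fell with starvation in control cells. Of 45 tested, 35 were lower (median log2 fold change -1.19, adjusted p = 1.9e-12 by camera; adjusted p = 0.0016 with an estimated correlation), and the median was -1.16 and -1.25 under the other scalings. In starved OGDH-depleted cells the median was 0.03, with 0 called by edgeR, 4 at an unadjusted p under 0.05 and 0 called by DESeq2. The interaction was positive for 21 of 45 (median 1.22, adjusted p = 0.00068 with an estimated correlation). Krüppel-like factors, zinc finger transcription factors, rose in 11 of 14 cases with starvation in control cells (median 1.37, adjusted p = 0.0072 with an estimated correlation), and 7 of 14 had a negative interaction (median -0.88, adjusted p = 0.016 with an estimated correlation). KLF2, KLF4 and KLF6 are also in the immediate early list and KLF10 and KLF11 in the MondoA list. The family is therefore in part the same result counted again.

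Replication histones fell with OGDH loss in glucose for 7 of 38 genes (median -0.72, adjusted p = 0.0060 with an estimated correlation) and without glucose for 19, with 3 higher (median -0.81, adjusted p = 0.048 with an estimated correlation). Their mRNAs lack poly-A tails, so how many are counted depends on the library, whose kind is not given in the sources used here. Mitochondrial tRNA transcripts were lower with starvation in depleted cells for 8 of 10 genes (median -3.01, adjusted p = 0.0045 with an estimated correlation), with an interaction of -2.55 for which 7 of 10 were lower (adjusted p = 1.9e-08; adjusted p = 0.062 with an estimated correlation). Proteasome subunits, 37 in all, had medians of 0.02 and -0.01 for starvation in control and in depleted cells.

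For the protocadherins in starved control cells, GC-dependent differences between libraries are argued against, since with a GC offset the median was -1.16 and 36 of 45 were lower. Reads shared between members through a common exon are argued against by the counting itself, which left out fragments overlapping several genes. The beta cluster, whose genes share no such exon, adds little to that. Its median was -1.19 with 12 of 16 lower (quartiles -1.86 and -0.99). A drop in transcription of these clusters, or faster loss of their mRNAs, in starved control cells may account for the pattern. This is a hypothesis found on the same data, and transcription and mRNA loss were not told apart by any test.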
